A study of Danio rerio with 33 samples.

How the data were processed

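Polyadenylated RNA was sequenced from 33 zebrafish samples in 11 groups of 3 biological replicates: 21 samples of embryos at the 10-somite stage in 7 groups and 12 gonad samples in 4 groups. Per the submitters' processing notes, RNA was extracted with TRIzol and made into stranded libraries from 100 ng of RNA each, reads were trimmed with Trimmomatic 0.36 and quantified against GRCz10 transcripts with kallisto 0.43.0, and normalization was done with edgeR. The deposited gene table holds estimated counts (expected counts from the authors' quantification) for 30490 genes, with 100% of the values above 0 not whole numbers, as such estimates are. The deposited transcript table holds estimated counts for 54435 transcripts. The deposited normalized table gives a signal in CPM, which the authors made by dividing gene counts by an effective library size, for 25374 genes. Each of its columns was the gene table's column times 1 constant, with a largest relative spread of 3e-08. It was used only as an alternative.

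All comparisons started from the deposited gene-level estimated counts, rounded to whole numbers. They were fitted with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter (minimum count 10, minimum total count 15), and robust quasi-likelihood F tests, with Benjamini-Hochberg adjustment over all genes tested and a two-sided threshold of 0.05. Embryos and gonads had a fit each. The embryo fit held 22305 genes, a biological coefficient of variation of 0.241, 14 residual degrees of freedom and scaling factors of 0.92 to 1.09. The gonad fit held 25870 genes, a biological coefficient of variation of 0.429, 8 residual degrees of freedom and scaling factors of 0.65 to 1.4. Fold changes are log2 values from these fits, their standard error (SE) is the log2 value divided by the square root of F, and group levels are means of TMM-scaled CPM with the standard deviation (SD) over 3 libraries. "Changed", "higher" and "lower" in counts of genes mean an adjusted p under 0.05. Libraries held 15152199 to 24131756 estimated counts. A gene with 0 counts in every library of a group was given a floor of 3 counts over the group, and the resulting bounds and the counting intervals (95% limits of a ratio of counts) cover counting error only. Genes are named by the symbols of the deposited table. Genomic positions are left out because the gene table used for neighbours describes another assembly, GRCz12tu.

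Comparisons, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. There were 13 planned contrasts, and 1 further contrast, the kctd15 effect averaged over the backgrounds without AP2, with AP2 and with AP2-P59, was added after the data were seen. The averaged contrast weighs the 3 effects equally. Named genes are of 4 kinds: kctd15a, kctd15b and the tfap2 genes; up to 8 changed genes with the largest rise and up to 8 with the largest fall among genes with a mean of at least 5 CPM in the higher group, no overlap between the compared replicates and a gene name rather than a clone or locus name (4 each way, overlap allowed, for differences of effects); up to 4 members with the smallest p of each list past its test; and a set of neural crest, epidermal and gonad markers. Where a gene outside this rule is named, that is said. Curated lists of tissue markers, signalling targets and stress responses were tested with limma 3.58.1 camera at the preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, when at least 5 members had been tested: 29 lists in embryos and 17 in gonads. The lists were also tested with camera at a correlation estimated from the data and with fry, which asks whether a list's genes move on balance in 1 direction. Counts of list members are given over all genes tested and "adjusted over the list alone". The planned lists of AP2-responsive genes had no members, since no gene passed in the AP2 or AP2-P59 contrasts, so lists of the 100 genes with the smallest p each way were used instead. This replacement was chosen after the calls were seen.

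Replicate numbers were checked for pairing by correlating, across genes, the deviations of equally numbered libraries from their group means. For each library these correlations with the libraries of other groups were averaged by replicate number, with 3 numbers to choose from. The library's own number had the highest mean in 20 of the 21 embryo libraries and 6 of the 12 gonad libraries. A contrast was taken as paired when the correlation was above 0.1 for every number, which held for kctd15, AP2, both co-injections and AP2-P59 against AP2, and did not hold for AP2-P59 against wild type, mutant embryos or the gonads. For paired contrasts a value from a fit with replicate number as a block stands beside some of the results that it changes. Lists that passed only with the block are not all given.

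Alternatives were RLE size factors in edgeR, no low-count filter, DESeq2 1.42.0, limma-trend on log2 of the deposited normalized CPM plus 1, the groups of a contrast alone, the replicate block, and leaving out each library in turn. Refits without a library for gene lists, and all alternatives for the averaged contrast, were added after the data were seen. In refits without a library the other libraries of the fit set the spread. The pipeline was tested on simulated data with the fitted spread of 2 contrasts. With 50 genes changed at each fold, the kctd15 simulation found 8%, 44%, 62% and 66% of genes changed 1.5, 2, 3 and 4-fold, with 5 false among 100 calls. The mutant ovary simulation found 0%, 2%, 8% and 10%, with 0 false among 10 calls by edgeR. A list of 15 genes lowered 2-fold passed camera in both simulations, and 3 of 100 unchanged lists passed an unadjusted threshold of 0.05 in each. Genes were simulated independently of each other and without replicate structure, so the preset correlation of camera was not tested by this. Each gene was simulated at its mean level over all libraries of its fit, so the mutant ovary simulation used levels averaged over ovary and testis.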

Results

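Gene expression was measured by sequencing polyadenylated RNA from zebrafish embryos at the 10-somite stage and from adult gonads, in 33 libraries of 15152199 to 24131756 estimated counts. The 7 embryo groups had 3 biological replicates each. They were wild type, 5 pg AP2, 5 pg AP2-P59, 100 pg kctd15, AP2 with kctd15, AP2-P59 with kctd15, and kctd15 mutants. No injection is named for the wild-type embryos in the labels, so they are called uninjected here. The 4 gonad groups, also of 3 replicates, were ovary and testis of wild-type and kctd15 mutant fish. Kctd15 is a BTB-domain protein known to inhibit neural crest formation and to bind the activation domain of AP2, a transcription factor of neural crest and epidermis. The labels name neither the AP2 paralog, the injected form of nucleic acid, the change in AP2-P59 nor the mutated kctd15 gene.

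Estimated counts of the kctd15a transcript NM_001006012 marked the kctd15 injections. Its mean was 333 estimated counts (range 201 to 495) after kctd15 alone and 442 (273 to 731) after AP2 with kctd15, against 11.3 (0 to 34) in uninjected embryos. After AP2-P59 with kctd15 the mean was 215, but the library labelled replicate 1 had 0 counts, and in that library sox10 (38.3 CPM), krt92 (838 CPM) and ndrg1a (15.8 CPM) also lay near the means of AP2-P59 alone (45.3 CPM for sox10). Other genes lay near the 2 other co-injected libraries, with scinla at 14.4 CPM (13.1 and 12.3 in those, at least 25.1 after AP2-P59 alone) and fam20cb at 4.73 CPM (4.79 and 4.05, at least 7.25), so whether or how much kctd15 this library received stays open. A second kctd15a transcript, XM_005163052, was at 27.4 CPM ± 6.7 (SD, n = 3) in uninjected embryos and 13.4 ± 5.3 after kctd15 alone. Together these transcripts fall short of the kctd15a gene level in uninjected embryos, so the gene also holds transcripts not shown. How reads are divided among the transcripts of a gene is an estimate, so a count of 0 for a single transcript is uncertain. At the gene level kctd15a did not pass the test in any kctd15 injection (log2 0.63, 0.88 and 0.53 in embryos without AP2, with AP2 and with AP2-P59). No AP2 injection was visible in the tfap2 genes: tfap2a was at 177 CPM ± 24 (SD, n = 3) after AP2 and 203 ± 38 after AP2-P59, against 170 ± 33 in wild type.

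**Figure D1:**
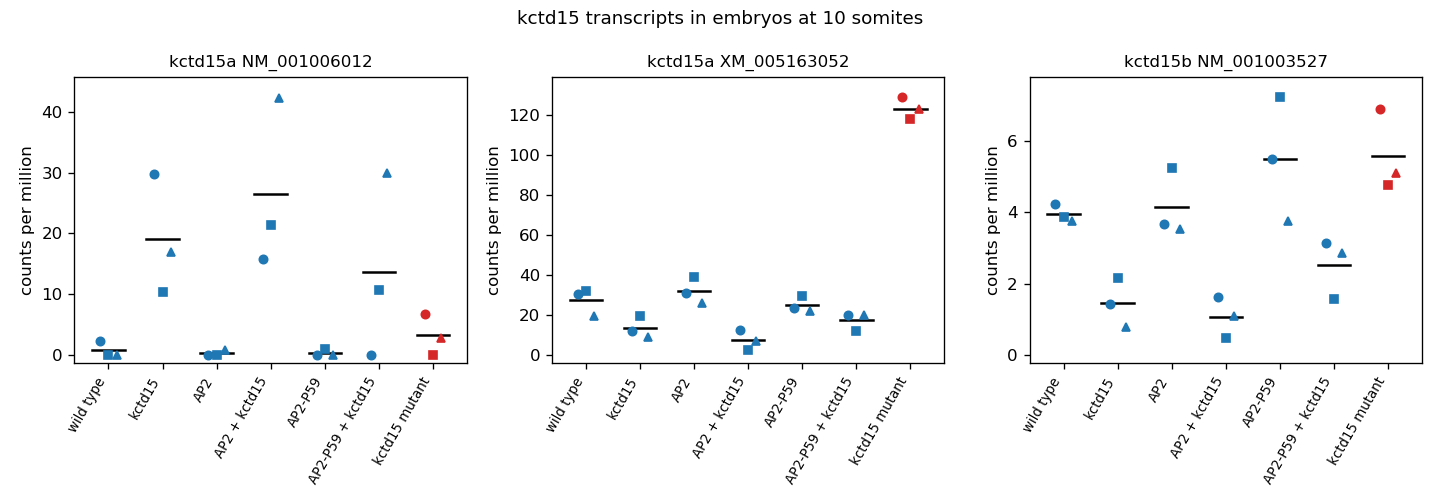
CPM of 3 kctd15 transcripts (1 panel each, linear vertical axis) in each embryo library of 7 groups; circles, squares and triangles are replicates 1, 2 and 3, black lines are group means, and mutants are red. The kctd15a transcript XM_005163052 averaged 123 CPM in mutants and 27.4 CPM in wild type, and NM_001006012 averaged 19 CPM after kctd15 alone and 0.74 CPM in wild type.

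The comparison of kctd15-injected with uninjected embryos asks what kctd15 alone does at this stage. Neural crest genes were lower as a group: the 13 measured members of the list of neural crest specifiers were all below wild type, with a median log2 of -0.5. Crestin, a marker of the whole neural crest in zebrafish, was at 62.7 CPM ± 10 (SD, n = 3) against 140 ± 18. The crest regulator sox10 was at 14.4 CPM ± 5.1 against 42 ± 4.5, and snai1b, a regulator of cell delamination, at 46.7 ± 5.3 against 81.9 ± 11. The receptor gene pdgfra was at 53.8 CPM ± 4.2 against 75.8 ± 2.7, and foxd3, an early crest regulator, at 16.2 ± 3.3 against 31.2 ± 6.7. No single gene passed the test over all genes (smallest adjusted p = 0.15), and 763 genes had an unadjusted p under 0.05 in edgeR. DESeq2 called 18 genes, limma-trend 1, and the edgeR fit with the replicate block 12 (2 higher, 10 lower), with crestin at adjusted p = 0.031 in that fit. The crest list passed camera (adjusted p = 1.1e-10) and 5 of its members were lower when adjusted over the list alone. With an estimated correlation the list had adjusted p = 0.11, and 0.071 with the block as well.

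Gene lists of other tissues also passed camera after kctd15 alone. The list of somite muscle genes was higher (median log2 0.34, 13 of 13 members up, adjusted p = 1.1e-05), with myog, a regulator of muscle differentiation, at log2 0.77 and the myosin light chain gene mylpfa at 0.94. Muscle genes were also higher after AP2-P59 against the same uninjected libraries (camera adjusted p = 0.043). They were lower when kctd15 was added to AP2-P59 (camera adjusted p = 0.049), so how much of their rise comes from kctd15 stays open. Notochord genes were higher (median 0.32, 8 of 9 up, adjusted p = 0.0018), among them the collagen gene col8a1a at 0.45. Blood and vessel genes were higher (median 0.3, 14 of 15 up, adjusted p = 9e-06), with spi1b, a myeloid regulator, at 0.93 and the globin gene hbbe3 at 1.76. Against the same uninjected libraries this list was as high after AP2 (0.28) and AP2-P59 (0.3), and Hox genes had like medians (0.14 after kctd15, 0.16 and 0.15), so these shifts cannot be ascribed to kctd15. Placode genes were lower (median -0.26, 13 of 15 down, adjusted p = 0.0012), with six4b at -0.57 and dlx3b at -0.68. Oocyte genes (-0.58, adjusted p = 0.0035), Hox genes (0.14, 0.031) and neural plate border genes (-0.09, 0.031) also passed camera. Border genes were lower after AP2 too against the same uninjected libraries (camera adjusted p = 0.016), so their shift cannot be ascribed to kctd15 either. No member of these lists passed over all genes, 1 blood gene and 1 muscle gene were higher and 1 placode gene lower when adjusted over the list alone, and with an estimated correlation the 7 lists had adjusted p = 0.11 to 0.71. The calls of 5 lists ended without 1 library: blood without kctd15 replicate 1 (adjusted p = 0.06), Hox without wild-type replicate 3 (0.88) or kctd15 replicate 1 (0.68), and border, oocyte and placode genes without wild-type replicate 1 (0.5, 0.8 and 0.15). Some of these calls also ended without kctd15 replicate 2 (adjusted p = 0.057 to 0.14) or kctd15 replicate 3 (0.07 to 0.17).

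The comparison of AP2 with kctd15 against AP2 alone asks what kctd15 does when AP2 is supplied, and it called 44 genes, 3 higher and 41 lower. Neural crest genes were again lower: crestin fell from 126 CPM ± 9 to 54.2 ± 13 (SD, n = 3; log2 -1.22, adjusted p = 0.025), snai1b fell by 1.03 on the log2 scale (adjusted p = 0.026) and pdgfra fell by 0.85 (adjusted p = 0.0016). Sox10 had the largest difference of the crest list (33.8 CPM ± 6.6 against 7.97 ± 5.4, log2 -2.08) with adjusted p = 0.11, and 0.011 with the replicate block. Keratin genes of the skin moved both ways. Krt17 fell from 690 CPM ± 91 to 54.5 ± 29 (log2 -3.66), krt92 from 958 ± 280 to 203 ± 74 (log2 -2.24) and cyt1l from 1690 ± 280 to 758 ± 140 (log2 -1.15), while krt97 rose from 260 ± 82 to 632 ± 83 (log2 1.28). The other 2 rises were ndrg1a, a gene known for its response to stress and differentiation (log2 1.42, adjusted p = 0.016), and ptpn22, a tyrosine phosphatase (log2 1.87, adjusted p = 0.047). The other named falls were scinla, an actin-severing protein of the gelsolin family (log2 -1.66, adjusted p = 0.00017), the proteoglycan gene ogn (-2.02), the collagen gene col16a1 (-1.89), the secreted kinase gene fam20cb (-1.78), aatka (-2.24, and -1.62 without AP2 replicate 2) and fam212aa (-2.2). Kctd15b was at 1.07 CPM ± 0.61 against 4.05 ± 0.76 (log2 -1.91), with adjusted p = 0.077, and 0.023 with the block.

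In the lists of this comparison, 3 of the 13 crest genes fell over all genes and 9 when adjusted over the list alone (median -0.85, adjusted p = 1.4e-16). The crest call held with an estimated correlation (adjusted p = 0.047). Of 21 epidermis and periderm genes 2 fell, krt92 and cyt1l, and 6 fell with 1 risen when adjusted over the list alone (median -0.33, adjusted p = 2e-05; 0.15 with an estimated correlation). Neural progenitor genes were higher (median 0.39, 11 of 11 up, adjusted p = 1.5e-06; 0.14 with an estimated correlation), with sox19a at 0.44 and gli3 at 0.4. Brain region genes (0.23), Hedgehog targets (0.21) and cell cycle genes (0.13) were higher, and placode genes (-0.27), blood and vessel genes (-0.19) and neuron genes (-0.1) lower, with adjusted p = 0.0059 to 0.049 in camera and 0.27 to 0.55 with an estimated correlation. Each of these last 6 calls ended without at least 1 library, at adjusted p = 0.051 to 0.21 without AP2 replicate 2, 0.12 to 0.16 without AP2 replicate 1, 0.057 to 0.15 without AP2 replicate 3, and 0.072 to 0.7, 0.23 to 0.57 and 0.1 to 0.47 without co-injected replicates 1, 2 and 3.

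Support for the 44 genes varied with the fit. The replicate block called 143 genes and DESeq2 151, each with all 44 among them, while a fit of these 6 libraries alone called 0 in edgeR (841 at an unadjusted p under 0.05). The count was 2 without co-injected replicate 2, 8 without AP2 replicate 2, and 20, 23 and 29 without co-injected replicate 1, AP2 replicate 3 and AP2 replicate 1. Scinla and pdgfra kept their calls without each library, and the other 13 named changed genes lost theirs without co-injected replicate 2 (adjusted p = 0.1 to 0.43).

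Adding kctd15 to AP2-P59 asks whether this form of AP2 responds differently. Neural crest genes were lower here too: crestin was at 70 CPM ± 19 (SD, n = 3) against 151 ± 48, pdgfra at 58.9 ± 5.7 against 88.1 ± 4.1, ets1 at 17.6 ± 1 against 27.6 ± 3.7 and snai1b at 58.2 ± 18 against 94.9 ± 12. Sox10 was at 23.9 CPM ± 13 against 45.3 ± 14. The crest list passed (median -0.58, 12 of 13 down, adjusted p = 1e-08; 0.2 with an estimated correlation), and 4 members were lower when adjusted over the list alone. Hedgehog targets were higher (median 0.22, 8 of 8 up, adjusted p = 0.00065; 0.2 with an estimated correlation), with nkx2.2a at 0.5 and hhip at 0.39. Presomitic mesoderm and tailbud genes were higher (0.29, adjusted p = 4.5e-05, and 0.13 without the library labelled co-injected replicate 1). Neuron (-0.18), oocyte (-0.54), placode (-0.22) and somite muscle genes (-0.17) were lower with adjusted p = 0.0028 to 0.049 (muscle 0.066 with the block), and all 5 of these lists had 0.45 to 0.66 with an estimated correlation. These 4 calls ended without at least 1 library, at adjusted p = 0.054 to 0.27 without AP2-P59 replicate 1, 0.12 without AP2-P59 replicate 3, and 0.062 to 0.77 and 0.065 to 0.18 without co-injected replicates 2 and 3. No gene passed over all genes in edgeR, with 906 at an unadjusted p under 0.05. DESeq2 called 16 genes, limma-trend 0, and the replicate block 13 (1 higher, 12 lower), with pdgfra at adjusted p = 0.025 and crestin at 0.036. Without the library labelled co-injected replicate 1, crestin had log2 -1.31 (adjusted p = 0.22) and sox10 -1.45 (adjusted p = 0.88), 0 genes passed (1209 at an unadjusted p under 0.05 in edgeR), and the crest list had adjusted p = 2.5e-12.

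The 3 kctd15 effects share no library, and they ran the same way for the genes called beside AP2. Of the 41 genes lower there, 40 were lower after kctd15 alone (median log2 -0.79) and 41 beside AP2-P59 (median -0.69), where 50% and 50.2% of all genes were lower. Averaged over the 3 backgrounds, a contrast chosen after the data were seen, kctd15 changed 117 genes, 17 higher and 100 lower. The crest genes crestin (log2 -1.17, SE 0.13, adjusted p = 0.00013), pdgfra (-0.64, 1.9e-05), snai1b (-0.85, 5e-04) and sox10 (-1.52, 0.0074) fell. Foxd3 (-0.78) and sox9b (-0.88) had adjusted p = 0.23 and 0.25, which became 0.0095 and 0.00038 with the block, and snai2 had log2 -0.2 (adjusted p = 0.81). In the skin krt17 (-2.3), krt92 (-1.49), cyt1l (-0.74) and the transglutaminase gene tgm1l4 (-2.02) fell, while krt97 (0.81), tgm5l (0.5) and the glycosyltransferase gene b3gnt5a (0.85) rose. Ndrg1a (1.13), the formin gene fmnl1 (1.22), ptpn22 (1.19), tprg1 (0.73) and the carbonic anhydrase gene cahz (0.6) also rose. Nme2a (-2.07), fam212aa (-1.5), aatka (-1.4), the placode gene six4b (-0.46) and kctd15b (-1.5, adjusted p = 0.0026) fell.

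Of the lists in the averaged contrast, the crest list had 6 of 13 members lower, 8 when adjusted over the list alone (median -0.64, adjusted p = 3.1e-23), and it held with an estimated correlation (adjusted p = 0.011). Placode genes had 1 of 15 lower, 5 when adjusted over the list alone (median -0.25, adjusted p = 1.1e-05; 0.34 with an estimated correlation). Epidermis and periderm genes had 2 of 21 lower, 7 with 1 higher when adjusted over the list alone (median -0.16, adjusted p = 5.8e-05; 0.14). Hedgehog targets (0.18) and neural progenitors (0.19) were higher, each at adjusted p = 5.8e-05 (0.081 and 0.14 with an estimated correlation). Oocyte genes (-0.45, 0.00063) and neuron genes (-0.09, 0.0021) were lower (0.14 and 0.34). Presomitic (0.12), Hox (0.11) and brain region genes (0.11) were higher at adjusted p = 0.0044, 0.024 and 0.027 (0.52 to 0.7 with an estimated correlation). Of these 10 lists only the crest, placode, oocyte and Hox lists also passed camera after kctd15 alone. The replicate block raised the count to 298 and DESeq2 to 227, and it was 95 to 154 without 1 library. Cahz and tprg1 lost their calls in most of these refits (adjusted p of up to 0.087 and 0.091), tgm5l without wild-type replicate 1 and kctd15 replicate 2 (0.052 and 0.054), and the presomitic, Hox and brain calls ended without AP2-P59 with kctd15 replicate 1 (adjusted p = 0.18 to 0.33), wild-type replicate 3 (0.12 to 0.28) and other libraries.

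**Figure D2:**
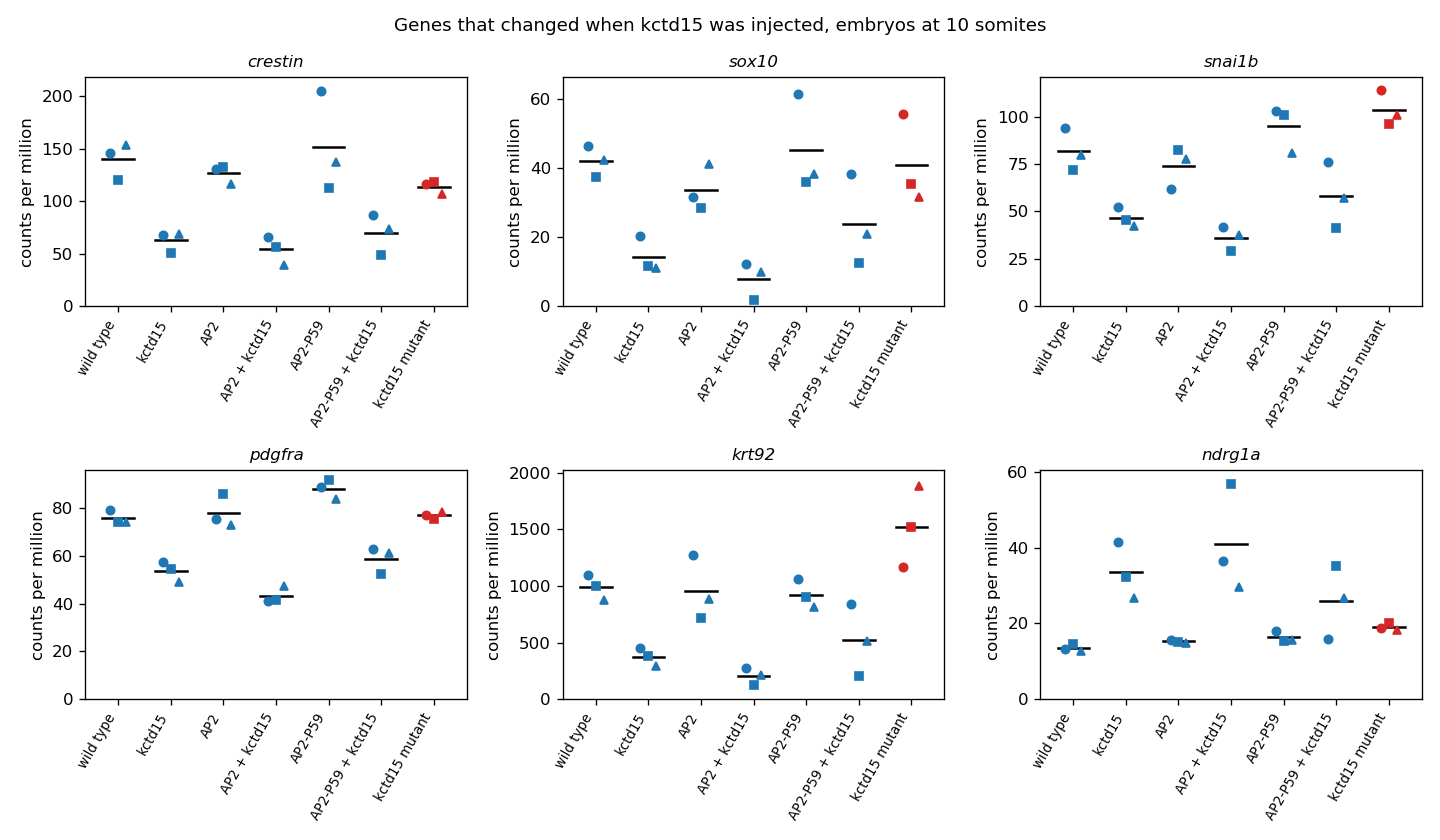
CPM of crestin, sox10, snai1b, pdgfra, krt92 and ndrg1a (1 panel each, linear vertical axis) in each embryo library; circles, squares and triangles are replicates 1, 2 and 3 and black lines are group means. Crestin averaged 126 CPM after AP2 and 54.2 CPM after AP2 with kctd15, and ndrg1a averaged 15.3 CPM and 41 CPM.

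**Figure D3:**
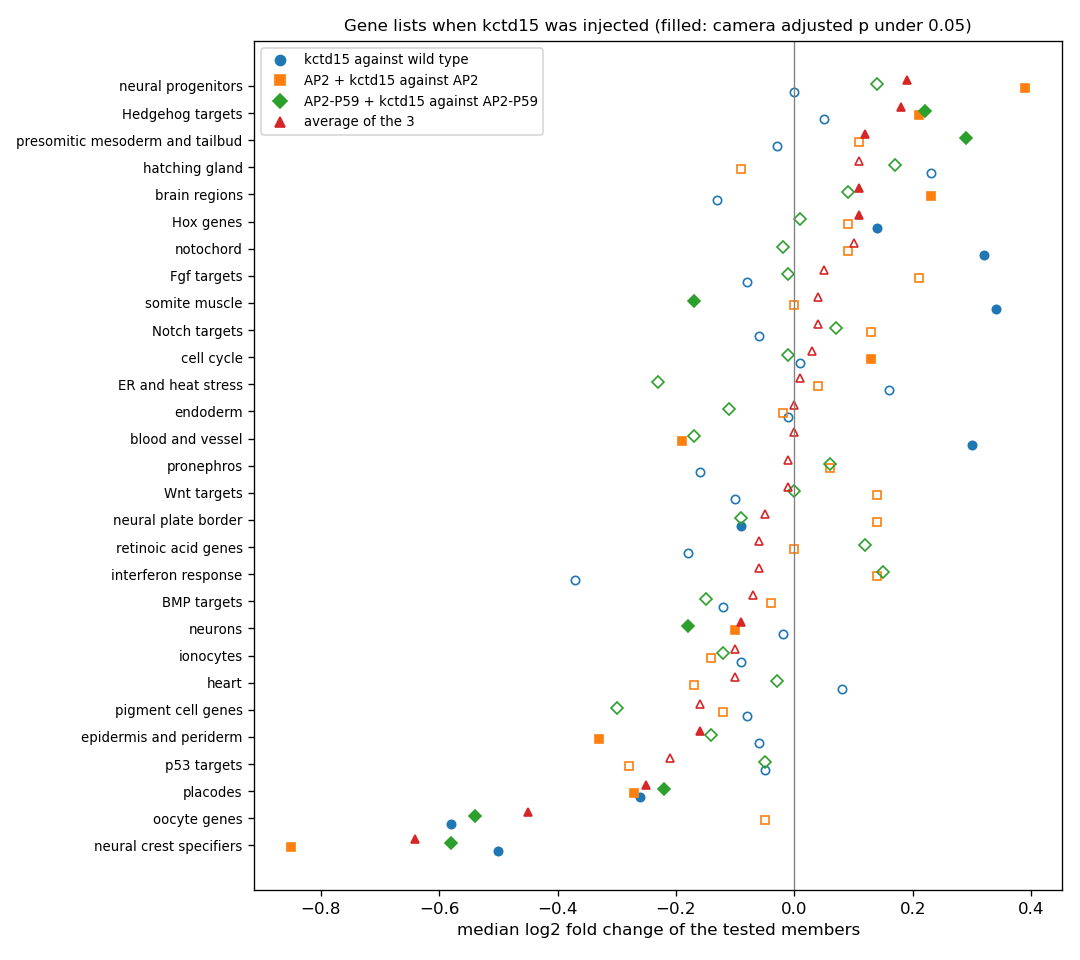
Median log2 fold change of 29 gene lists for kctd15 alone, with AP2, with AP2-P59 and on average; filled points have a camera adjusted p under 0.05 at the preset correlation. Neural crest specifiers had medians of -0.5, -0.85, -0.58 and -0.64.

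The difference between the kctd15 effects asks directly whether AP2 and AP2-P59 respond unequally. With AP2 against with AP2-P59 no gene passed in edgeR, DESeq2 or limma-trend (555 at an unadjusted p under 0.05 in edgeR), and sox10 had a difference of log2 -1.15 (SE 0.65) and crestin -0.11 (SE 0.31). Without the library labelled AP2-P59 with kctd15 replicate 1 the differences were -0.62 for sox10 and 0.09 for crestin, a change of sign (adjusted p = 1 each), and 0 genes passed (680 at an unadjusted p under 0.05 in edgeR). The crest list differed by a median of -0.26 (adjusted p = 0.061, and 0.025 with the block; 0.91 with an estimated correlation). Neural progenitors (0.23, 10 of 11 up, adjusted p = 0.061) and cell cycle genes (0.14, 15 of 15 up, 0.061) likewise passed only with the block (0.01 and 0.025; 0.91 each with an estimated correlation). With AP2 against without it, no gene passed with any of the 3 tools (652 at an unadjusted p under 0.05 in edgeR), and 11 lists passed camera but none with an estimated correlation (adjusted p = 0.17 to 0.46). This difference also holds any effect of injection, since the effect without AP2 is read against uninjected embryos. Among the 11 lists blood and vessel genes had a difference of -0.47 (adjusted p = 7.8e-07; 0.17 with an estimated correlation) and neural progenitors 0.35 (0.0022; 0.38). The blood call held without each library, and the other 10 ended without at least 1, at adjusted p of up to 0.42 without co-injected replicate 1, 0.35 without co-injected replicate 2, 0.11 without co-injected replicate 3, 0.13, 0.15 and 0.1 without AP2 replicates 1, 2 and 3, 0.31, 0.075 and 0.32 without kctd15 replicates 1, 2 and 3, and 0.12, 0.33 and 0.084 without wild-type replicates 1, 2 and 3.

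AP2 alone and AP2-P59 alone were compared with uninjected embryos to find what each form changes, and no gene passed for either in edgeR. After AP2, 745 genes had an unadjusted p under 0.05, the block called 1 gene and DESeq2 and limma-trend 0. After AP2-P59, 1199 genes had an unadjusted p under 0.05, and DESeq2 called 11 genes and limma-trend 0. Crestin was at 126 CPM ± 9 (SD, n = 3) after AP2 and 151 ± 48 after AP2-P59, against 140 ± 18. Heat shock genes stood out after AP2-P59: hsp70.2 was at 62 CPM ± 56 against 6.3 ± 2.8 and hsp70.1 at 31.6 ± 22 against 3.59 ± 2.1. The list of endoplasmic reticulum and heat stress genes passed (median 0.34, adjusted p = 0.002; 0.095 with an estimated correlation) with 3 members higher when adjusted over the list alone. Hedgehog targets were lower after AP2-P59 (median -0.32, 8 of 8 down, adjusted p = 0.00015; 0.095), with nkx2.2a at -0.75 and hhip at -0.45, and 2 members lower when adjusted over the list alone. The comparisons that add kctd15 to AP2 or AP2-P59 are read against these same AP2 and AP2-P59 libraries. Opposite shifts of a list there, as for Hedgehog targets, may therefore come in part from those libraries.

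Ionocyte genes were higher after AP2-P59 (median 0.61, adjusted p = 0.0087), with foxi3a and foxi3b, regulators of ionocyte fate, at log2 0.7 and 0.74, and after AP2 (0.41, adjusted p = 0.039, and 0.057 with the block). When adjusted over the list alone 3 ionocyte genes were higher and 2 progenitor and 2 brain region genes lower after AP2-P59. Neural progenitors were lower after both (-0.16 and -0.23; adjusted p = 0.0087 and 0.0097), as were brain region genes (-0.1 and -0.23; 0.021 and 0.0097), and blood and vessel genes were higher after both (0.3 and 0.28; 0.0099 and 4.6e-05). After AP2-P59 neuron (0.14) and muscle genes (0.1) were also higher (adjusted p = 0.046 and 0.043). After AP2 Hox genes were higher (0.16), and neural plate border genes (-0.17) and Hedgehog targets (-0.2) lower (adjusted p = 0.016 to 0.044). None of these 13 further calls held with an estimated correlation (adjusted p = 0.16 to 0.71), and these contrasts share the wild-type libraries, from which part of the likeness may come. Apart from blood after AP2, each of the 13 ended without at least 1 library. Among the highest adjusted p were 0.9 for Hox without wild-type replicate 3, 0.24 for border genes without wild-type replicate 1, 1 for muscle without wild-type replicate 2, 0.34 for neurons without AP2-P59 replicate 1, 0.3 for brain regions without AP2-P59 replicate 3 and 0.24 for Hedgehog targets without AP2 replicate 2. Compared directly, AP2-P59 against AP2 gave 0 genes in edgeR, DESeq2 and limma-trend (292 at an unadjusted p under 0.05) and 1 with the block. Of its lists, neural plate border (0.23, adjusted p = 0.0051), crest (0.26, 0.04) and heat stress genes (0.14, 0.033) were higher and Hedgehog targets (-0.13, 0.016) and hatching gland genes (-0.2, 0.016) lower. Without AP2-P59 replicate 1 these 5 had adjusted p = 0.078 to 0.76, and with an estimated correlation 0.33 to 0.95.

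The genes that moved most after either AP2 form were then read in the other form's kctd15 comparison, which shares no library with their choice. Of the 100 genes highest after AP2-P59, 73 moved down when kctd15 was added to AP2 (median log2 -0.161; 47.7% of all genes did), and of the 100 lowest 75 moved up (0.118; 52.2%). Of the 100 genes highest after AP2, 68 moved down when kctd15 was added to AP2-P59 (-0.077; 50.2%), and of the 100 lowest 79 moved up (0.182; 49.8%). All 4 medians were opposite in sign to the AP2 effect. In fry, the test named beforehand, 1 of the 4 lists, the genes lowest after AP2, passed an unadjusted threshold of 0.05. All 4 passed it in camera at the preset correlation. Further lists held the 100 genes highest and the 100 lowest on average over both AP2 forms. They were read in the kctd15 effect with AP2 minus that with AP2-P59, which shares libraries with their choice. Medians were 0.085 and -0.097, with 37 genes of each list opposite to the AP2 effect (49.5% and 50.5% of all genes). These signs are those of a smaller reversal beside AP2 than beside AP2-P59. Neither list passed fry at that threshold and both passed camera.

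Kctd15 mutant embryos were compared with wild-type embryos to find what differs with the mutation, and 912 genes passed, 303 higher and 609 lower, 591 of them at least 2-fold. Kctd15a itself rose from 48.9 CPM ± 8.7 to 189 ± 9.3 (SD, n = 3; log2 1.95, SE 0.39, adjusted p = 0.0087), and its transcript XM_005163052 was at 27.4 CPM ± 6.7 in wild type and 123 ± 5.5 in mutants. The largest named rises were the ammonium transporter gene rhcga (0.461 CPM ± 0.33 to 16.7 ± 9.5, log2 5.13), the transcription factor gene cebp1 (1.02 ± 0.74 to 27.1 ± 4.5, log2 4.7) and crhbp, which encodes a binding protein of corticotropin-releasing hormone (log2 4.18). The relaxin receptor gene rxfp2a rose from 1 CPM ± 0.28 to 12.6 ± 2.5 (adjusted p = 4.1e-05). Ttc21a (4.05), the RNA-binding protein gene pcbp3 (3.69), the cadherin gene cdh13 (3.64) and the vitellogenin gene vtg7 (3.09) rose as well. Gna13a, a G protein subunit, had 0 counts in the 3 mutant libraries and 5.61 CPM ± 0.71 in wild type, at least 94-fold lower. The elongation factor gene eef2a.2 fell from 41.7 CPM ± 4.5 to 4.46 ± 1.1 (log2 -3.22), the phosphatase subunit gene ppp6r2 from 12.2 ± 3.4 to 1.15 ± 0.19 (-3.4) and maptb, which encodes a tau protein, from 7.69 ± 0.78 to 1.17 ± 0.055 (-2.71). Znf664 (-4.98), the calcium channel gene cacna1ba (-4.55), the lysyl oxidase gene loxl2b (-3.08) and dock8 (-2.95) also fell. Cacna1ba varied widely among embryos without the mutation, from 2.74 CPM in AP2 replicate 1 to 128 CPM in wild-type replicate 2. In mutants it was at 2.6 to 3.75 CPM. The neural crest genes did not pass: crestin was at 114 CPM ± 5.5 against 140 ± 18, sox10 at 40.9 ± 13 against 42 ± 4.5 and foxd3 at 56.1 ± 11 against 31.2 ± 6.7.

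**Figure D4:**
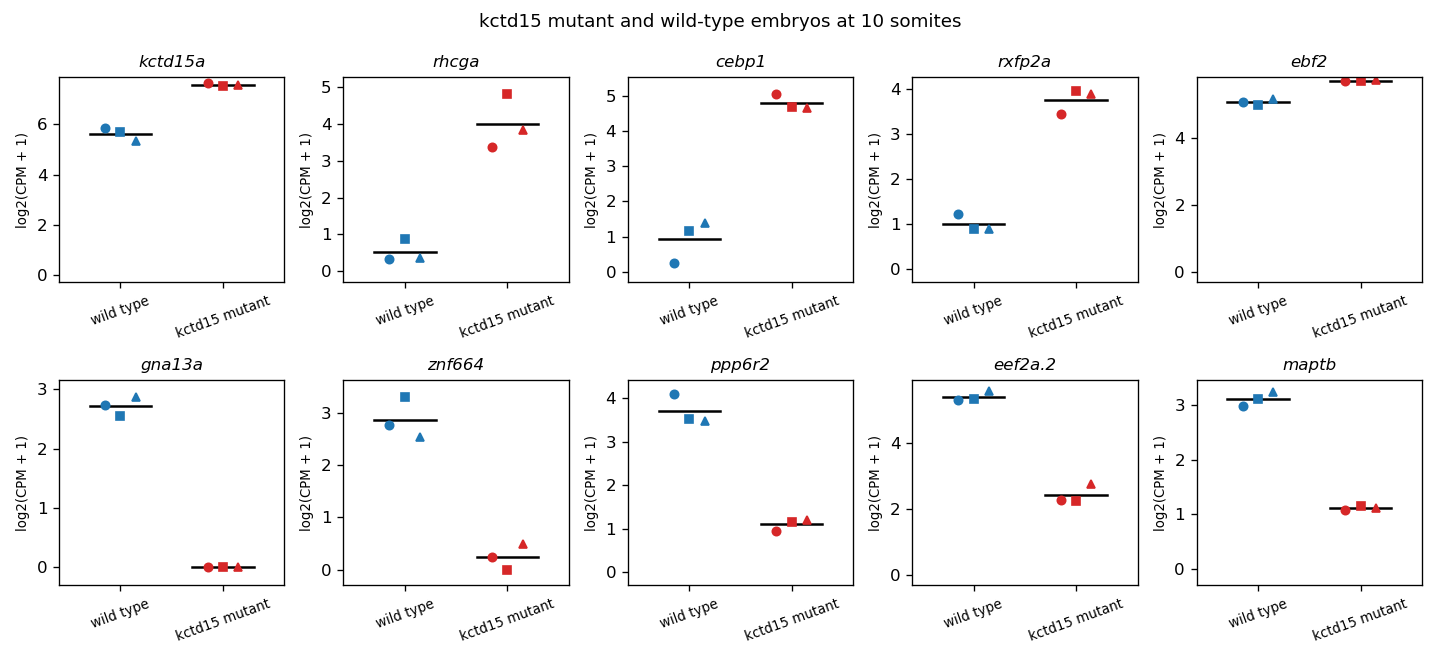
Log2 of CPM plus 1 of 10 genes in each wild-type and kctd15 mutant embryo library (3 per group); points are libraries and lines are means of the log2 values. Kctd15a averaged 48.9 CPM in wild type and 189 CPM in mutants, and eef2a.2 41.7 CPM and 4.46 CPM.

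Among the gene lists of mutant embryos 7 passed camera, and each of these calls was lost with an estimated correlation (adjusted p = 0.82). Epidermis and periderm genes were higher (median log2 0.27, 16 of 21 up, adjusted p = 0.017), with the keratin genes cyt1 (0.84) and cyt1l (0.83) risen and 3 members risen when adjusted over the list alone. Neuron genes were higher (median 0.34, adjusted p = 0.037) with 1 of 15 risen, ebf2, a regulator of neuronal differentiation (0.64, adjusted p = 0.0085), and 3 higher and 1 lower when adjusted over the list alone. Hox (0.33), presomitic and tailbud (0.29), neural plate border (0.23) and Wnt target genes (0.27) were higher with adjusted p = 0.016 to 0.043, with her7 at 0.7, pax3a at 0.47, hoxb3a at 0.34 and sp5l at 0.65. The p53 targets were lower (median -0.37, adjusted p = 0.027), with bbc3, an inducer of cell death, at -1.52 and cdkn1a, an inhibitor of the cell cycle, at -1.52. No member of these last 5 lists passed over all genes or adjusted over the list alone. All 7 calls ended without wild-type replicate 3 (adjusted p = 0.092 to 0.19) and 6 without mutant replicate 1 (0.17 to 0.24), and 1 each without wild-type replicate 1 (0.15) and wild-type replicate 2 (0.14).

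The count of 912 in mutant embryos was 263, 339 and 520 without mutant replicates 3, 2 and 1, and 364 and 442 without wild-type replicates 3 and 2. DESeq2 gave 1642 (659 higher, 983 lower), and the replicate block 2931 (1345 higher, 1586 lower). Equally numbered mutant and wild-type libraries correlated at 0.26, 0.16 and 0.06 for numbers 1, 2 and 3. They thus fell short of the pairing rule only for number 3. Of the 20 named changed genes 14 kept their calls in the refits without a library, and kctd15a and vtg7 lost theirs without wild-type replicate 3 (adjusted p = 0.051 each). Cacna1ba, dock8, cyt1 and cyt1l lost theirs without mutant replicate 3 (0.066 to 0.21) or mutant replicate 2 (0.054 to 0.12), and some of them without the other libraries (0.05 to 0.17). Some sizes moved more than 1.5-fold without 1 library, with rhcga at log2 5.9 without wild-type replicate 2, crhbp at 4.94 without wild-type replicate 1, ttc21a at 5.03 without wild-type replicate 3, znf664 at -6.06 without mutant replicate 3, cacna1ba at -3.91 without wild-type replicate 2 and loxl2b at -3.86 without mutant replicate 1.

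Mutant and wild-type ovaries were compared to find what differs with the mutation in the adult gonad, and 143 genes passed, 90 higher and 53 lower. In ovary and testis, as in embryos, the design does not separate the mutation from the line that carries it. The AP2 gene tfap2a fell from 31.9 CPM ± 7.5 to 6.32 ± 2.9 (SD, n = 3; log2 -2.33, adjusted p = 0.019). Hmcn2, an extracellular matrix protein gene, fell from 34.4 CPM ± 7.7 to 1.14 ± 0.13 (log2 -4.9, adjusted p = 1e-04) and ryr2a, a calcium release channel gene, from 80.3 ± 41 to 3.51 ± 1.7 (-4.52). Btr22 (-4.23), depdc7 (-4.03), tmed1b (-4.02), the sugar transporter gene slc2a11a (-3.89), the signalling adaptor gene shc3 (-3.85) and fam101b (-3.43) fell as well. Nfil3-3 rose by log2 6.94, at 0.382 CPM in mutant replicate 3 and at least 17 in the other mutants, and anpepb, a peptidase gene, by 6.17, at 4.25, 10.9 and 69.9 CPM in mutant replicates 1, 2 and 3 (4.26 without mutant replicate 3, adjusted p = 0.016). Other named rises were layna (5.74), the ferlin gene fer1l6 (5.39) and cadpsb, a gene of secretory vesicle release (4.95). Anxa6, an annexin gene, rose from 4.42 CPM ± 1.9 to 47.1 ± 17, the T cell gene cd28 from 4.52 ± 2 to 48.9 ± 13, and the transcription factor gene sox21a from 4.71 ± 2.6 to 66.7 ± 41. Kctd15b was at 0.609 CPM ± 0.4 against 3.35 ± 1.5 (log2 -2.48, adjusted p = 0.13).

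Of the ovary lists, steroid synthesis genes were lower (median log2 -0.67, 12 of 15 down, adjusted p = 0.0017; 0.38 with an estimated correlation). In this list hsd17b3, a steroid dehydrogenase gene, fell (-1.68, adjusted p = 0.048), 3 members fell when adjusted over the list alone, and star, the cholesterol carrier of steroid synthesis, was at 1.44 CPM ± 1.1 against 16.9 ± 19 (SD, n = 3). Follicle cell genes (median -0.51, adjusted p = 0.021; 0.38) and genes of Sertoli cells, the support cells of the testis (-0.61, 0.038; 0.38), were lower, with 1 member of each fallen when adjusted over the list alone. Among them were the hormone receptor gene lhcgr at -1.9 and amh at -1.18. Germ cell and piRNA genes were higher (0.55, adjusted p = 0.029; 0.57), with tdrd1 at 0.82 and piwil1 at 0.66. The library of mutant replicate 3 stood apart, with 89200 CPM of the yolk precursor gene vtg1 against at most 2480 in the other ovaries, and all 14 liver and vitellogenin genes and all 7 gut and pancreas genes at least 4-fold above each of the others. Without this library 128 genes passed, 91 of them among the 143, and the steroid list had a median of -1.06 (adjusted p = 0.0016), the follicle list -0.63 (0.012), the Sertoli list -0.66 (0.021) and the germ cell list 0.5 (0.019). The liver and vitellogenin list, at 5.09 (adjusted p = 0.79) with all libraries, had a median of -5.51 (adjusted p = 4.1e-05) without this library, where the liver gene fabp10a was at 44.3 CPM in wild-type replicate 1 and at most 2.27 in the other ovaries.

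The ovary calls rested on few libraries. The count was 33 without wild-type replicate 2 and 78 without wild-type replicate 3, 23 when the 6 ovary libraries were fitted alone, and 1070 in DESeq2. Of the 18 named changed genes 9 kept their calls without each library, and the other 9, tfap2a and hsd17b3 among them, lost theirs without wild-type replicate 2 (adjusted p = 0.056 to 0.13). Some of these 9 also lost theirs without wild-type replicates 1 and 3 (0.052 to 0.081 and 0.075 to 0.1) or mutant replicates 1, 2 and 3 (0.065, 0.051 to 0.087 and 0.058 to 0.091). Nfil3-3 had log2 6.07 (adjusted p = 0.056) without mutant replicate 2, layna 6.94 without wild-type replicate 1 and slc2a11a -4.98 without mutant replicate 1. The follicle, Sertoli and germ cell calls ended without mutant replicate 2 (0.086 to 0.18), and some of them without wild-type replicates 2 (0.069 to 0.081) and 3 (0.067).

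Mutant and wild-type testes differed in 18 genes, 7 higher and 11 lower. Ppp1r32 fell from 57.6 CPM ± 18 to 0.25 ± 0.12 (SD, n = 3; log2 -7.82, adjusted p = 0.00069) and pkd1b, a polycystin gene, from 33.7 ± 7.1 to 2.09 ± 0.26 (-4.01, adjusted p = 0.00069). The small heat shock gene cryabb (-4.15) and the tripartite motif genes btr22 (-3.96) and btr20 (-2.91) fell, and btr07 (3.6) and the tropomyosin gene tpm4b (1.85) rose. Extracellular matrix genes were lower as a list (median -1.09, 12 of 12 down, adjusted p = 5.7e-07; 0.34 with an estimated correlation), with the fibronectin gene fn1a at 9.48 CPM ± 4 against 33.4 ± 9.1 and 1 member fallen when adjusted over the list alone. Leukocyte genes were lower (-0.88, adjusted p = 0.0019; 0.5), with ptprc at -1.73, and Sertoli cell genes were lower (-0.35, 0.0062; 0.34), with amh at 110 CPM ± 19 against 284 ± 88 and gsdf at 436 ± 13 against 867 ± 220. When adjusted over the list alone 1 leukocyte gene, 1 red blood cell gene and 2 Sertoli genes fell. Red blood cell genes (-1.35, adjusted p = 0.022; 0.7) and cell cycle genes (-0.22, 0.019; 0.34) were lower and interferon response genes higher (1.22, 0.009; 0.7), with mxb at 133 CPM ± 120 against 22.9 ± 9.9. Kctd15a (log2 0.6) and kctd15b (-0.67) did not pass.

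The count of 18 was 5 without mutant replicate 2, 5 without mutant replicate 3 and 7 without wild-type replicate 2, and limma-trend gave 160 and DESeq2 302. A fit of the 6 testis libraries alone gave 7. Ppp1r32 and pkd1b kept their calls without each library, and the other 5 named genes lost theirs without mutant replicate 3 (adjusted p = 0.11 to 0.27), mutant replicate 2 (0.083 to 0.26), wild-type replicate 2 (0.12 to 0.17) and wild-type replicate 1 (0.077 to 0.12), and 4 of them without the other libraries (0.059 to 0.09). The matrix list kept its call without each library. The others ended without mutant replicate 1 (leukocytes 0.11, red blood cells 0.21), mutant replicate 2 (interferon 0.34, cell cycle 0.14), mutant replicate 3 (cell cycle 0.082), wild-type replicate 1 (0.062 to 0.081 for 3 lists), wild-type replicate 2 (red blood cells 0.24) or wild-type replicate 3 (Sertoli 0.059, cell cycle 0.056).

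**Figure D5:**
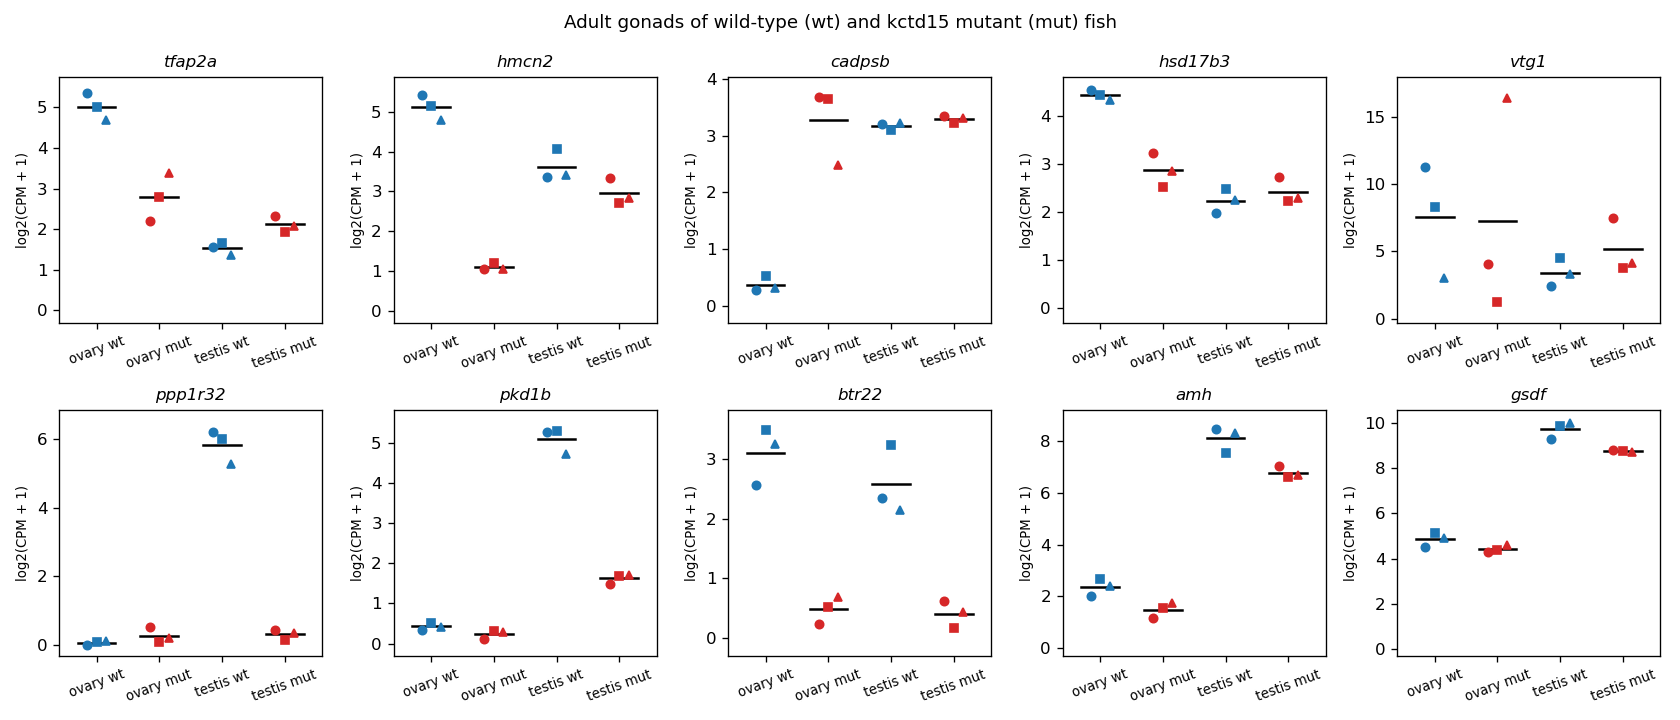
Log2 of CPM plus 1 of 10 genes in each gonad library (4 groups of 3); points are libraries and lines are means of the log2 values. Tfap2a averaged 31.9 CPM in wild-type and 6.32 CPM in mutant ovary, and ppp1r32 57.6 CPM in wild-type and 0.25 CPM in mutant testis.

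The mutant effect differed between testis and ovary in 21 genes, 6 higher and 15 lower in testis relative to ovary. Hmcn2 had a difference of log2 4.16 (SE 0.48, adjusted p = 0.0053) and ppp1r32 of -9.72 (SE 1.1, adjusted p = 0.0055), with ppp1r32 at no more than 0.442 CPM in any ovary library, so that the size of its difference is uncertain. Layna (-5.37, and -6.57 without wild-type ovary replicate 1), fer1l6 (-5.19) and cadpsb (-4.82) differed as well. Extracellular matrix genes differed by a median of -1.54 (12 of 12 down, adjusted p = 0.00083) and germ cell genes by -0.75 (adjusted p = 0.013), both at 0.68 with an estimated correlation. Tfap2a had a difference of 3.15 (adjusted p = 0.066, and 0.021 without mutant ovary replicate 3). The count was 7 and 8 without mutant testis replicates 3 and 2, 10 without wild-type ovary replicate 3 or wild-type testis replicate 1, 11 without wild-type testis replicate 2, 12 without wild-type ovary replicate 2 or mutant ovary replicate 1, and 13 without wild-type testis replicate 3 or mutant ovary replicate 2. DESeq2 gave 399 and limma-trend 68. Hmcn2 kept its call without each library, ppp1r32 lost it without mutant ovary replicate 1 (log2 -8.78, 0.078), cadpsb without wild-type ovary replicate 3 and mutant testis replicates 2 and 3 (0.056 to 0.062), and layna and fer1l6 without most of the 12 libraries (0.053 to 0.16). The matrix call ended without mutant ovary replicate 1 (0.06), and the germ cell call without mutant ovary replicate 2 (0.055) and mutant testis replicate 2 (0.078).

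Wild-type testis and ovary were compared as a check of tissue identity, and 18235 of 25870 genes passed, 10763 higher and 7472 lower in testis. The median log2 over all genes was 0.725 with TMM and 0.713 with RLE scaling, so changes read relative to that shift. Egg coat genes marked the ovary: zp3.2 was at 2610 CPM ± 670 (SD, n = 3) against 0.878 ± 0.53 in testis, and all 17 oocyte genes, with bmp15 and buc among them, were lower in testis (adjusted p = 1.2e-12). All 20 spermatid and flagellum genes were higher in testis (adjusted p = 2.6e-08), with the tektin gene tekt1 at 326 CPM ± 56 against 0.702 ± 0.2 and the sperm fusion gene izumo1 at 78.2 ± 3.2 against 0.0454 ± 0.079 (counting interval of the ratio 440 to 13100). Lrp2bp and klhl10a had 0 counts in ovary and were at least 755-fold and 511-fold higher in testis. Meiosis genes had 10 of 11 members higher (sycp3 256 CPM ± 23 against 1.14 ± 0.35), and Sertoli cell genes 7 of 9 (dmrt1 179 ± 27 against 0.772 ± 0.18). Interferon response genes had 11 of 12 higher and cell cycle genes 2 higher and 9 lower, with mcm3 at log2 4.26 and ccnb1 at -3.31. These 6 lists had adjusted p = 1.2e-12 to 0.04 in camera and 0.072 to 0.72 with an estimated correlation, and the cell cycle call ended without wild-type ovary replicate 3 or wild-type testis replicate 2 (0.051 each). Kctd15a was higher in testis (2.78 CPM ± 1 against 0.0958 ± 0.11; log2 4.74, and 6 without wild-type ovary replicate 2), as was tfap2c (35 ± 2.2 against 10.4 ± 4.1), and tfap2a was lower (1.9 ± 0.32 against 31.9 ± 7.5).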

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

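The counts over other splits of the samples were planned, and the tests of the 3 patterns (mutant embryo genes, liver and pancreas transcripts, neural crest genes) were chosen after the results were seen.

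The kctd15 effect with AP2 differed from that without AP2 in 11 gene lists by a test of the difference itself, which also holds any effect of injection, as the effect without AP2 is read against uninjected embryos. The median log2 difference was -0.47 for blood and vessel, -0.47 for somite muscle, -0.2 for epidermis and periderm, -0.2 for hatching gland and -0.16 for neural crest genes. It was 0.35 for neural progenitors, 0.23 for brain regions, 0.22 for the neural plate border, 0.18 for Fgf targets, 0.17 for Wnt targets and 0.16 for presomitic genes. With an estimated correlation these lists had adjusted p = 0.17 to 0.46. The mutant effect differed between testis and ovary in 21 genes by the same kind of test, with log2 differences of 4.16 for hmcn2, -9.72 for ppp1r32, -5.37 for layna, -5.19 for fer1l6 and -4.82 for cadpsb. Extracellular matrix genes differed by a median of -1.54 and germ cell genes by -0.75 (adjusted p = 0.68 each with an estimated correlation). In the transcript table, which the comparisons of genes do not use, the kctd15a transcript NM_001006012 had group means above its wild-type mean of 11.3 estimated counts (range 0 to 34). The means were 442 (273 to 731) with AP2 and kctd15, 333 (201 to 495) with kctd15 alone, 215 (0 to 473) with AP2-P59 and kctd15, and 58 (0 to 121) in mutants. The ranges with AP2-P59 and kctd15 and in mutants overlapped that of wild type.

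For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 912 and 0 genes for mutant embryos, 44 and 0 for kctd15 added to AP2, 143 and 10 for mutant ovary, 18 and 3 for mutant testis, and 18235 and 0 for testis against ovary, with 1 split of 10 as large as the real one in each. Where edgeR called 0 genes, all 10 splits were necessarily as large, and the highest other was 0 for kctd15 alone, 1 for AP2, 0 for AP2-P59, 0 for AP2-P59 against AP2 and 2 for kctd15 added to AP2-P59. Among splits that part all 3 replicate pairs, the highest count was 0 for each of these 5 and for kctd15 added to AP2. For the mutant effect in testis against ovary, 2 of 100 splits, the real one included, gave at least 21 genes, unadjusted for the number of contrasts. The other, with 23 genes, exchanged the mutant and wild-type ovary libraries completely. Such splits still hold real differences, so these counts do not by themselves exclude chance. For the averaged kctd15 effect 2 of 100 gave at least 117. The highest other, 653, had the 6 libraries of replicate 2 on 1 side, which points to a structure of the samples by replicate number, and the fit with the replicate block gave 298. For the kctd15 effect with AP2 against with AP2-P59 and against without AP2, each with 0 genes, 100 of 100 splits were necessarily as large and say nothing about chance, and the highest were 197 and 12. The 197 genes point to a structure of the samples that was not identified.

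The 912 genes of mutant embryos may come in part from differences around the mutated gene or in the mutant line. Linkage as the whole cause was argued against: 9.1% of the 770 changed genes with a known chromosome lay on the chromosomes of kctd15a and kctd15b in the GRCz12tu gene table. Of all tested genes with a known chromosome 6.2% lay there. As part of the cause, the 50 tested neighbours on each side of both genes had an odds ratio of 1.83 (Fisher's exact Holm p = 0.085), those of kctd15a 1.24 (0.61) and those of kctd15b 2.45 (0.049; 9 of 96 changed, with wtip, unc13c and p2ry6 among them); a first version tested both genes together with fewer genes placed and did not pass, and the division by gene and the bound were written after its values were seen. Differences of like size in every tissue of the line, as the whole cause, would move nearly all changed genes the same way in both gonads. This was not seen. Of the changed genes 54.2% moved the same way in mutant ovary, where 49.5% of the unchanged genes did. In mutant testis the shares were 61.4% and 52.8%. Genes scarce in a gonad have no readable sign there, so these shares do not decide whether such differences were the whole cause. Such differences fit as part of the cause (odds ratio 1.21 in ovary, Fisher's exact p = 0.0062, and 1.42 in testis, 5.5e-07). Line differences that show in only some tissues, or are too small for their sign to be read in gonads, were not tested. An effect of kctd15 itself stays open, since the design does not separate the mutation from the line that carries it, and the neighbours named here were chosen after their values were seen.

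Liver and pancreas transcripts in mutant ovary replicate 3 may come from tissue taken with the ovary: 100% of the members of both lists (14 and 7 genes) were at least 4-fold above each other ovary library, with fabp10a at 1360 CPM against at most 44.3 and try at 1160 against at most 98.5. A sample of another organ under the label was argued against by the oocyte genes, whose median ratio to the other ovaries was 0.965. The library as the source of the mutant ovary genes was argued against by the 91 of 143 genes that passed without it. No biological explanation was tested.

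The lower neural crest genes after kctd15 are a candidate effect of kctd15. The injection itself was argued against, since the list's median was -0.85 between co-injected and AP2-injected embryos, both injected, and -0.04 between AP2-injected and uninjected embryos. A p53 response to more injected material was argued against only weakly by the p53 list. Its median was -0.21 in the averaged contrast, where the list did not pass camera. A weaker effect beside AP2-P59 than beside AP2 cannot be told apart from an equal one, with adjusted p = 0.91 for the list difference with an estimated correlation and 3 libraries per group. Other effects of the larger amount injected stay open, as no group received as much of another material.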

How the results depend on the processing

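The alternatives for the averaged contrast and the refits of lists without a library were chosen after the data were seen. No result past its threshold changed direction under any alternative, while some genes and lists short of it did, such as somite muscle after kctd15 added to AP2 with the replicate block (adjusted p = 0.89 and 0.97). RLE size factors and no low-count filter left all 14 counts of genes within 1.5 times.

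With the replicate block the counts became 2931 for mutant embryos (1345 higher, 1586 lower), 12 for kctd15 alone, 1 for AP2, 1 for AP2-P59 against AP2, 143 and 13 for kctd15 added to AP2 and to AP2-P59, 298 for the average, 10 for mutant testis and 13 for the testis and ovary difference. With DESeq2 they were 1642 for mutant embryos (659 higher, 983 lower), 18 for kctd15 alone, 11 for AP2-P59, 151 and 16 for kctd15 added to AP2 and to AP2-P59, 227 for the average, 1070 for mutant ovary, 302 for mutant testis and 399 for the difference. With limma-trend they were 1 for kctd15 alone, 160 for mutant testis and 68 for the difference. With the groups of a contrast alone they were 0 for kctd15 added to AP2, 23 for mutant ovary and 7 for mutant testis. Without 1 library the counts ranged from 263 to 756 for mutant embryos, 2 to 32 for kctd15 added to AP2, 95 to 154 for the average, 33 to 142 for mutant ovary, 5 to 24 for mutant testis, 7 to 23 for the difference and 16864 to 17414 for testis against ovary. Apart from the smaller number of libraries in these last 2 settings, the cause was not tested.

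Among named genes, DESeq2 added 31 calls and ended 0, the replicate block added 40 and ended 11, the groups alone ended 32 and added 2, and refits without a library ended 186 and added 12. In the list tests the estimated correlation ended 88 calls, fry ended 80 and added 7, and refits without a library ended 190. Simulations at this number of libraries found 44% of 2-fold changes in embryos and 2% in ovary, the latter at levels averaged over ovary and testis. Counts near 0 therefore do not show that genes were unchanged.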

Other observations

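The test of the genes that moved most after AP2 or AP2-P59 was written before its values were seen, and the lists themselves and the genes shared between mutant tissues were chosen after the calls were seen.

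One hypothesis tested was that kctd15 moves AP2-responsive genes back. Of 4 lists of 100 genes, 1 passed fry at an unadjusted 0.05 where all 4 were required, all 4 passed camera at the preset correlation, and all 4 medians had the opposite sign to the AP2 effect. Lists chosen over both AP2 forms were read in the difference of the kctd15 effect between AP2 and AP2-P59. Their medians were 0.085 for the higher and -0.097 for the lower genes, the signs of a smaller reversal beside AP2. Neither of these lists passed fry, and both passed camera. The hypothesis stays open.

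In mutant embryos and mutant ovary 14 genes passed in both, where 4.6 were expected by chance, and 9 of the 14 moved in the same direction, which was not tested against chance. Anxa6, dchs1b, iqgap2, layna and LOC103909608 moved in opposite directions. In mutant embryos and testis 5 genes passed in both, all 5 in the same direction. LOC100535918 (log2 -2.23, -5.46 and -4.71 in embryo, ovary and testis) and LOC103909985 (-8.41, -8.57 and -8.08) fell in all 3 mutant tissues.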
